A study of Drosophila melanogaster with 18 samples.

How the data were processed

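Per the labels' protocols, larvae were kept at 25 °C, 200 larvae were pooled per replicate, and total RNA was extracted with TRIzol and RNeasy, labelled with biotin and hybridised by the standard Affymetrix procedure. The deposited values are log2 signals that, per the submitters' processing notes, were made with RMA, and the range of the values fits that scale. The version and settings of RMA and the genome build are not given in the sources used here. Each of the 18 arrays gave 18952 values.

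Probe sets were assigned to genes with the annotation table supplied with the series. Of the probe sets, 13647 named 1 gene, 402 named several, 4720 named none and 183 were controls. Names of 13544 were matched in the reference table, giving 11982 genes, of which 1094 had several probe sets. For those the probe set with the highest mean was kept. A gene was tested if at least 3 arrays reached a log2 value of 6, which left 8211 genes, 8193 of them with a position in Release 6 of the assembly. Of these, 55 lay on chromosome 4, 129 in pericentromeric regions and 0 on the Y chromosome.

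Gene changes were estimated with limma 3.58.1 in R 4.3.3, with the 5 groups in 1 linear model, moderated variances, 13 residual degrees of freedom and Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. Groups of genes were tested with limma camera at the preset correlation of 0.01, and again with a correlation estimated from the residuals. camera compares moderated t statistics of genes, not the mean log2 changes printed beside its p, which can point the other way. Scores per array (mean of the group minus mean of the other genes) were compared by an exact two-sided permutation test. For position and length, p was adjusted over the comparisons, and for gene lists over the 25 lists with enough tested members.

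The 27 lists covered targeted genes, heterochromatin and chromatin factors, ribosomal and mitochondrial ribosomal proteins, oxidative phosphorylation, proteasome, glycolysis, DNA replication and cell cycle, antimicrobial and humoral immune genes, chaperones, detoxification, digestive enzymes, cuticle proteins, muscle, neuronal, haemocyte, fat body, germline and spermatogenesis genes. They also covered yolk and chorion genes, ecdysone, dosage compensation and sex determination, apoptosis and DNA damage, Hox and other Polycomb targets, Y-linked genes, and named pericentromeric and chromosome 4 genes. The lists, comparisons, filter, tests and alternatives were fixed before the data were examined, except where a test is said to have been chosen later. Genes were named by a rule: the targeted genes, the 8 largest rises and 8 largest falls among called genes whose arrays did not overlap between groups, and up to 4 members of each list or region with the largest called changes.

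Pairing by replicate letter was checked from the arrays, since the labels give letters without saying that they mark shared batches. Same-letter residual correlations exceeded 0.1 throughout for HP1a, Setdb1 and Su(var)3-9 mutants against wildtype, for the arrays labelled HP1a Pof double mutant against HP1a mutants, and for HP1a against Setdb1 mutants, with lowest values of 0.334, 0.27, 0.105, 0.423 and 0.271. The other comparisons had lowest values of 0.0784, -0.05 and -0.01. No comparison was paired in the main fit. The letter entered as a block only in an alternative, which is reported for the comparisons above 0.1. No mutant array has the letters D to F, so in that alternative wildtype arrays D to F did not enter the comparisons with wildtype.

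The procedure was tested on simulated data with 8211 independent genes, 200 of them changed per comparison. It recovered 53.7% to 77.6% of changes of 0.5, 85.1% to 95.5% of changes of 1 and at least 95.5% of changes of 2, with 6 to 14 false calls. A set of 55 genes shifted by 0.2 gave camera p between 1.03e-24 and 1.31e-15, and an unshifted set gave p between 0.101 and 0.803.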

Results

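Whole first-instar larvae of Drosophila melanogaster were collected about 48 hours after egg laying, and total RNA from 200 larvae per replicate was hybridised to 18 one-colour Affymetrix arrays. There were 6 wildtype arrays, labelled A to F, and 3 arrays, labelled A to C, for each of 4 mutant genotypes. These were mutants of HP1a (a heterochromatin protein), and of Setdb1 and Su(var)3-9 (each a histone methyltransferase). The remaining genotype was the HP1a Pof double mutant (Pof encodes a protein that coats chromosome 4). Per the labels, HP1a and Su(var)3-9 mutants carry different alleles on the paired chromosomes, and Setdb1 mutants the same allele on each. The double mutants carry the HP1a alleles with the same Pof allele on each. The labels do not say whether any protein is absent. The title of the series asks how these proteins act on genes of different genomic position, length and expression pattern. Each array gave 18952 log2 values with medians between 5.93 and 6.03, and 8211 genes were bright enough to be tested. The number of arrays limits the precision of every value below.

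Wildtype arrays resembled each other more closely than mutant arrays did. Pairwise correlations across tested genes ran from 0.987 to 0.996 among wildtype arrays and from 0.901 to 0.992 among arrays of the same or different mutant groups. The mean correlation with arrays of the same group was 0.992 in wildtype and between 0.972 and 0.980 in the mutant groups. The first principal component held 55.4% of the variance and set the 6 wildtype arrays (scores 38.6 to 46.9) apart from all mutant arrays, whose group means lay between -25.3 and -15.9. The second, with 18.7%, set Su(var)3-9 mutant arrays B (-35.6) and C (-46.0) apart, while array A of that group lay at -15.6. Control probe sets moved with genotype as well: the 3' probe set for 18S ribosomal RNA averaged 12.30 ± 0.09 (SD, n = 6) in wildtype and 9.39 ± 0.20 (n = 3) in HP1a mutants. The 3'-minus-5' signal difference over 3 control transcripts, a sign of RNA integrity, was 1.67 ± 0.15 (n = 6) in wildtype, 1.64 ± 0.26 in HP1a mutants, between 1.43 and 1.54 in the arrays labelled HP1a Pof double mutant, 1.25 ± 0.09 in Setdb1 mutants and 1.32 ± 0.13 in Su(var)3-9 mutants (n = 3 each).

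The gene for HP1a, on chromosome arm 2L, was lower in both genotypes that carry its alleles. Its log2 level was 9.48 ± 0.07 (SD, n = 3) in HP1a mutants and 9.53 ± 0.08 (n = 3) in the arrays labelled HP1a Pof double mutant, against 10.20 ± 0.05 (n = 6) in wildtype, 10.13 ± 0.15 in Setdb1 mutants and 10.11 ± 0.05 in Su(var)3-9 mutants. Against wildtype it fell by 0.72 and by 0.68, with limma adjusted p = 3e-07 and 4.61e-07, in 3 of 3 arrays of each group. Pof went against its label: its probe set read 8.32 ± 0.29 in the arrays labelled HP1a Pof double mutant, against 7.05 ± 0.05 in HP1a mutants, 6.99 ± 0.09 in Setdb1 mutants, 7.61 ± 0.64 in Su(var)3-9 mutants and 7.49 ± 0.09 in wildtype. Against wildtype Pof rose by 0.83 in the arrays of that label and fell by 0.50 in Setdb1 mutants (limma adjusted p = 0.00104 and 0.0323), the latter not called with the replicate letter as a block (-0.57, adjusted p = 0.0715). Whether this probe set lies inside the part of Pof that the allele removes is not given in the sources used here, so the higher signal does not check the label, and every direction drawn from these 3 arrays carries that limit. The Setdb1 and Su(var)3-9 genes themselves were not analysed here.

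The comparison of HP1a mutants with wildtype asks which genes differ in level between these larvae. Cuticle protein genes rose and digestive and detoxification genes fell, on a background of small changes in most of the transcriptome. Of 8211 genes, 1929 were higher and 2926 lower at an adjusted p under 0.05 (limma), 466 and 532 of them by at least 2-fold. Centring each array on the median of its genes gave 2461 higher and 2575 lower. Large rises included the cuticle protein genes Cpr49Ad (log2 change 5.35 ± 0.16, SE) and Cpr67Fa2 (4.21 ± 0.33), nol (5.11 ± 0.39) and Drsl2 (4.37 ± 0.30), a gene of the antifungal drosomycin family. CG43117 (6.32 ± 0.78), CG9259 (6.10 ± 0.15) and CG42816 (5.82 ± 0.40) rose furthest. The largest falls included the zinc transporter gene Zip42C.2 (-5.47 ± 0.22), the cytochrome P450 genes Cyp12d1-d (-4.95 ± 0.11) and Cyp4p1 (-4.74 ± 0.12), the immune effector gene BomS4 (-3.54 ± 0.14) and PGRP-SC2 (-3.43 ± 0.10), which encodes a peptidoglycan-degrading amidase. In each of these genes the 3 mutant arrays did not overlap the 6 wildtype arrays, as in 1749 higher and 2771 lower genes of all those tested (2.38% by chance).

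Among the gene lists, 60 of 85 cuticle protein genes rose in HP1a mutants and 6 fell (64 and 7 adjusted over the list alone). Their mean rose by 1.69 relative to the other genes, with Cpr62Bc at 3.72 ± 0.48 and Cpr100A at 3.67 ± 0.46 (limma camera adjusted p = 1.5e-11, and adjusted p = 0.623 with an estimated correlation). Of 38 digestive enzyme genes, 32 fell and 2 rose (33 and 2 adjusted over the list alone), with a relative mean of -0.99 (adjusted p = 2.34e-07, and adjusted p = 0.623 with an estimated correlation). The gut lipase gene mag (-2.68 ± 0.21) and the trypsin genes kappaTry (-2.45 ± 0.13), lambdaTry (-2.41 ± 0.18) and iotaTry (-2.37 ± 0.19) led that list. Of 92 glutathione S-transferase and cytochrome P450 genes, 63 fell and 16 rose (65 and 16 adjusted over the list alone), with a relative mean of -0.62 (adjusted p = 3.05e-05, and adjusted p = 0.623 with an estimated correlation). Cyp6w1 fell by 3.03 while Cyp28a5 rose by 2.76. In all 3 lists the mean of every HP1a mutant array lay outside the wildtype range. These lists moved together with the 18S signal described above, which was lower on the same arrays.

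Further lists were called higher in HP1a mutants with smaller shifts. Mitochondrial ribosomal protein genes (26 of 69 rose, 2 fell, 24 and 2 adjusted over the list alone) had a relative mean of 0.18, led by mRpS31 (0.69 ± 0.07) and mRpS6 (0.67 ± 0.08), with limma camera adjusted p = 0.000494, and adjusted p = 0.963 with an estimated correlation. Of 24 neuronal genes, 10 rose and 3 fell (9 and 2 adjusted over the list alone), among them VAChT (2.10 ± 0.25) and VGlut (1.06 ± 0.13), which load acetylcholine and glutamate into synaptic vesicles. That list's adjusted p was 0.0202, with adjusted p = 0.963 with an estimated correlation, and it was not called without HP1a mutant array A (0.27, adjusted p = 0.121). A filter at log2 8 (0.37, limma adjusted p = 0.113), means of probe sets (0.34, adjusted p = 0.0568) and array weights (0.31, adjusted p = 0.0579) ended that call too. Of 14 Hox and other Polycomb target genes, 9 rose and 0 fell (9 and 0 adjusted over the list alone), including Antp (0.54 ± 0.15) and Dfd (0.51 ± 0.12), with adjusted p = 0.013, and adjusted p = 0.623 with an estimated correlation. Of 12 chaperone genes, 7 rose and 2 fell (7 and 2 adjusted over the list alone), with Hsc70-5 at 0.81 ± 0.09 and Hsp27 at 0.75 ± 0.14. The adjusted p of that list was 0.0249, with adjusted p = 0.623 with an estimated correlation and 0.0552 with the replicate letter as a block (shift 0.30). Of 31 heterochromatin and chromatin factors, 3 rose and 5 fell (3 and 4 adjusted over the list alone). Su(var)2-10, a SUMO ligase gene, rose by 0.78 and HP1c fell by 0.60, while the list as a whole was not called (limma adjusted p = 0.377). Oxidative phosphorylation genes (3 of 60 rose and 30 fell, the same adjusted over the list alone; -0.09) and DNA replication and cell cycle genes (11 of 24 rose and 3 fell, the same adjusted over the list alone; 0.24) were not called (limma adjusted p = 0.074 and 0.0522). Without a filter both were (-0.09 and 0.22, limma adjusted p = 0.0463 and 0.0462), and the second also without wildtype array A (0.26, adjusted p = 0.0285) or D (0.24, adjusted p = 0.0448).

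By position, genes on chromosome 4 rose in HP1a mutants relative to the rest of the genome. Over 55 genes the mean was 0.31 above that of the other genes, and 18 rose and 7 fell (18 and 7 adjusted over the list alone). Their own mean change was 0.26 and their median 0.09, against a median of -0.06 over all tested genes. The ring finger gene Rnf11 rose by 2.94 ± 0.27, the Pax6 homologue toy by 1.66 ± 0.22, Ephrin by 1.52 ± 0.08 and the transcription factor gene NfI by 1.29 ± 0.19. All 3 mutant arrays lay above all 6 wildtype arrays (0.50 ± 0.10 against 0.18 ± 0.05, SD; exact two-sided permutation p = 0.0119, the smallest that 84 splits can give). Arms 2L, 2R and 3L (relative means -0.04, -0.09 and 0.09) and the pericentromeric genes had the same permutation p, so complete separation did not mark out chromosome 4. Arrays of all mutant groups lay above wildtype here (lowest 0.275, highest wildtype array 0.262), parted as on the first principal component. Comparisons with wildtype therefore cannot tell effects of the mutations on chromosome 4 from a difference common to the wildtype arrays. limma camera gave adjusted p = 0.00453, and adjusted p = 0.587 with an estimated correlation, and the mean lay at percentile 99.73 of 10000 random lists matched on level. A list of 37 named chromosome 4 genes, all of them among these 55 and so no separate support, had 11 up and 4 down (11 and 4 adjusted over the list alone; relative mean 0.25, adjusted p = 0.0316, and adjusted p = 0.963 with an estimated correlation), but was not called without HP1a mutant array A (0.18, adjusted p = 0.162). That call also ended with a filter at log2 8 (0.19, limma adjusted p = 0.136), array weights (0.22, adjusted p = 0.0597) and wildtype arrays A to C alone (0.22, adjusted p = 0.0544). The 129 genes in pericentromeric regions had a relative mean of -0.09 that was not called (limma adjusted p = 0.386); 25 rose and 50 fell (24 and 50 adjusted over the list alone), with CG40160 at -2.61 ± 0.15, CG40298 at -2.43 ± 0.25 and the chitin deacetylase gene Cda4 at 2.09 ± 0.21. Of 14 named pericentromeric genes 1 rose and 5 fell (1 and 5 adjusted over the list alone), led by Maf1 (-1.10 ± 0.10), a repressor of RNA polymerase III, and cta (-0.60 ± 0.12), and that list was not called (limma adjusted p = 0.316).

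Long genes rose relative to short genes in HP1a mutants. With genes parted into 5 equal groups by length, the mean change of the longest group (1602 genes of at least 7946 bp) was 0.12, and that of the shortest group (1602 genes of at most 1286 bp) was -0.08, a difference of 0.20. Among the longest, 499 rose and 329 fell, and among the shortest, 315 rose and 729 fell. limma camera gave adjusted p = 4.61e-07, and adjusted p = 0.359 with an estimated correlation; the exact two-sided permutation p over arrays was 0.0238. The 3'-minus-5' signal difference given above was 1.64 in HP1a, 1.25 in Setdb1 and 1.32 in Su(var)3-9 mutants and 1.67 in wildtype. The length differences of these mutants from wildtype were 0.20, -0.02 and -0.17. The arrays labelled HP1a Pof double mutant had the largest length difference, 0.34, at 3'-minus-5' values between 1.43 and 1.54. Those values lay below the HP1a mutant mean, so the mutant groups were not in the same order on both measures. Whether length and RNA integrity were related was not tested.

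**Figure D1:**
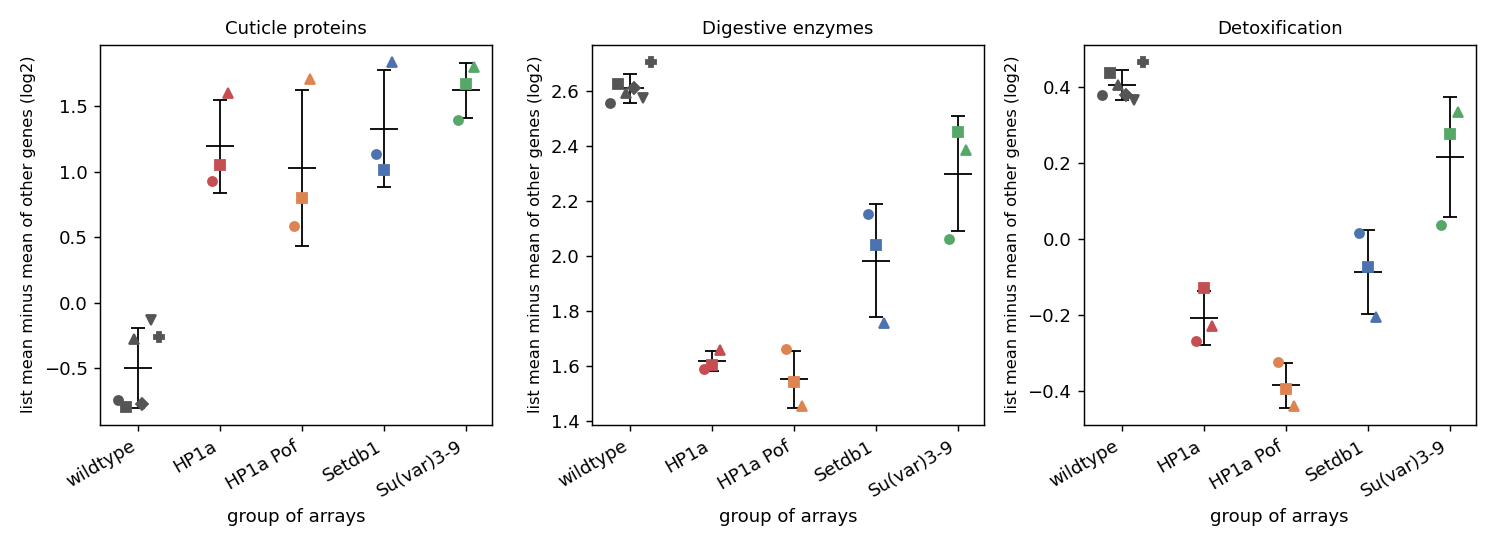
Mean log2 level of cuticle protein, digestive enzyme and detoxification genes minus that of all other tested genes, on each of 18 arrays (circle, square and triangle are replicates A to C, diamond, inverted triangle and plus are D to F; lines give the group mean and SD). The cuticle mean is at most -0.13 in wildtype and at least 0.58 in every mutant array, and the digestive and detoxification means of all mutant arrays lie below the wildtype range.

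Setdb1 mutants were compared with wildtype in the same way. The same 3 gene groups moved, with cuticle genes higher and digestive and detoxification genes lower. Of 8211 genes 1419 were higher and 2889 lower (limma), 413 and 364 by at least 2-fold. The median gene lay at -0.11, and centring each array on the median of its genes gave 2105 higher and 2174 lower. Arrays of the groups did not overlap for 49.8% of genes (2.38% by chance). Large rises included CG42816 (6.45 ± 0.40), CG14851 (5.73 ± 0.92), Drsl2 (4.78 ± 0.30) and Arc1 (4.11 ± 0.10), which encodes a capsid-forming neuronal protein. Large falls included CG16898 (-5.75 ± 0.15), the peroxiredoxin gene Prx6c (-5.75 ± 0.20), Zip42C.2 (-5.47 ± 0.22), Cyp12d1-d (-5.39 ± 0.11) and lectin-24A (-4.86 ± 0.13). All of these exceeded the shift of the median gene many times over.

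In Setdb1 mutants 63 of 85 cuticle protein genes rose and 6 fell (64 and 6 adjusted over the list alone). Their relative mean was 1.82, with Cpr23B at 3.77 ± 0.41 and Lcp65Ad at 3.75 ± 0.52 (limma camera adjusted p = 1.3e-17, and adjusted p = 0.931 with an estimated correlation). Of the digestive enzyme genes, 26 fell and 6 rose (27 and 6 adjusted over the list alone; relative mean -0.63, adjusted p = 0.00857, and adjusted p = 0.959 with an estimated correlation). mag fell by 4.04 and the maltase genes Mal-A8 and Mal-A6 fell by 3.21 and 2.68. Of the detoxification genes, 56 fell and 13 rose (57 and 14 adjusted over the list alone; relative mean -0.49, adjusted p = 0.00118, and adjusted p = 0.959 with an estimated correlation), with Cyp6a14 at -3.11 ± 0.13. Mitochondrial ribosomal protein genes rose in 34 of 69 cases and fell in 0 (34 and 0 adjusted over the list alone; relative mean 0.25, adjusted p = 3.86e-09, and adjusted p = 0.959 with an estimated correlation). Of 9 glycolytic genes 6 rose and 1 fell (6 and 1 adjusted over the list alone), led by the hexokinase gene Hex-A (0.73 ± 0.09) and Pgk (0.42 ± 0.07). The glycolysis list had adjusted p = 0.02, and adjusted p = 0.959 with an estimated correlation, and was not called without Setdb1 mutant array B (0.26, adjusted p = 0.0577). Among 31 chromatin factors 4 rose and 12 fell (4 and 12 adjusted over the list alone; limma adjusted p = 0.89, not called). wde, whose product is a cofactor of Setdb1, rose by 0.97 and the insulator genes su(Hw) and BEAF-32 fell by 0.84 and 0.64. The 3' 18S control signal was 9.92 ± 1.10 (SD, n = 3) on these arrays.

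Chromosome 4 genes again lay above the rest of the genome in Setdb1 mutants, by 0.17, with 13 up and 13 down (13 and 13 adjusted over the list alone). Rnf11 (2.82 ± 0.27), Ephrin (1.60 ± 0.08) and Pur-alpha (1.45 ± 0.10) rose, while the zinc transporter gene Zip102B fell by 3.95. All 3 arrays lay above all wildtype arrays (exact two-sided permutation p = 0.0119, as for arms 2L, 2R, 3L and 3R), with limma camera adjusted p = 0.019, and adjusted p = 0.587 with an estimated correlation. The mean lay at percentile 95.15 of random lists matched on level. The call ended with the replicate letter as a block (0.14, limma adjusted p = 0.0607) and without Setdb1 mutant array A (0.13, adjusted p = 0.0666). Pericentromeric genes had a relative mean of 0.08, with 2 of 3 arrays above the wildtype range, and were not called (limma adjusted p = 0.386): 25 rose and 37 fell (25 and 32 adjusted over the list alone). The Tweedle cuticle genes TwdlV (2.64 ± 0.33) and TwdlG (2.24 ± 0.33) and l(3)80Fg (2.11 ± 0.12) rose most. The longest and shortest groups did not differ by the test (mean difference -0.02, median difference 0.06, adjusted p = 0.0945, exact permutation p = 0.821). The sign of that mean turned without Setdb1 mutant array C (0.06, limma adjusted p = 0.005) and without wildtype array A (0.000439, adjusted p = 0.0471). These p come from camera, which compares t statistics, so they do not test whether such a mean differs from 0.

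In Su(var)3-9 mutants the cuticle genes rose furthest of the 3 single genotypes in mean log2 terms, and more tested genes were lower than higher. Over all probe sets the array medians lay at 5.97 to 6.02, against 5.93 to 5.98 in wildtype, so the median over all probe sets was not lower. The interquartile range was narrower, at 3.45 ± 0.22 (SD, n = 3) against 3.72 ± 0.05 (n = 6), with array C at 3.20. Of 8211 genes, 1337 were higher and 3910 lower than in wildtype (limma), 455 and 589 by at least 2-fold. The median gene lay at -0.22, and centring each array on the median of its genes gave 2396 higher and 2355 lower. Non-overlap held for 56.8% of genes (2.38% by chance). Lcp9 (7.20 ± 0.27), Cpr67Fa2 (5.93 ± 0.33) and Cpr49Ad (5.44 ± 0.16), all cuticle protein genes, and the salivary glue genes ng3 (6.03 ± 0.63) and ng2 (5.61 ± 0.64) were among the largest rises. CG43677 (-5.14 ± 0.51), CG3819 (-3.71 ± 0.21), the cuticle protein gene Cpr47Ed (-3.64 ± 0.39) and Cyp6w1 (-3.60 ± 0.29) were among the largest falls.

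Of the 85 cuticle protein genes 68 rose and 6 fell in Su(var)3-9 mutants (70 and 7 adjusted over the list alone), with a relative mean of 2.12 in 3 of 3 arrays above wildtype (limma camera adjusted p = 6.54e-24, and adjusted p = 0.228 with an estimated correlation). Of 12 chaperone genes 7 rose and 1 fell (7 and 1 adjusted over the list alone), with Hsp27 at 1.86 ± 0.14, Hsp26 at 1.54 ± 0.19 and Hsp68 at 1.05 ± 0.20. That list had a relative mean of 0.64 (adjusted p = 0.00144, and adjusted p = 0.228 with an estimated correlation). Of the digestive enzyme genes 22 fell and 6 rose (22 and 6 adjusted over the list alone), with kappaTry at -2.56 ± 0.13 and the amylase-related gene Amyrel at 2.58 ± 0.18. Of the detoxification genes 55 fell and 17 rose (56 and 17 adjusted over the list alone). Neither list was called (relative means -0.31 and -0.19, limma adjusted p = 0.598 and 0.593), although all 3 arrays lay below all wildtype arrays in both (exact two-sided permutation p = 0.0119). Without Su(var)3-9 mutant array A the relative means of digestive enzymes and detoxification were -0.19 and -0.10. Of 21 muscle genes 9 rose and 6 fell (9 and 6 adjusted over the list alone), with Obsc at 0.70 ± 0.12 and Act88F at -1.15 ± 0.23. The mean of the muscle list was -0.01, its median 0.17 and its relative mean 0.15 (adjusted p = 0.0469, and adjusted p = 0.999 with an estimated correlation), and it was not called with the replicate letter as a block (0.10, adjusted p = 0.115). Leaving out Su(var)3-9 mutant array A (0.06, limma adjusted p = 0.184) or wildtype array A, D or F (0.15, 0.14 and 0.12, adjusted p = 0.0561, 0.0604 and 0.0644) also ended that call, and cyclic loess turned its sign (-0.00461). Among chromatin factors 2 rose and 17 fell (2 and 17 adjusted over the list alone; not called, limma adjusted p = 0.647), with HP6 at 1.05 ± 0.15 and su(Hw) at -1.11 ± 0.14. The 3' 18S control signal was 10.10 ± 0.47 (SD, n = 3).

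Chromosome 4 genes in Su(var)3-9 mutants were 0.26 above the other genes, with 18 up and 17 down (18 and 17 adjusted over the list alone). Their own mean change was 0.10 and their median -0.15. Rnf11 (3.49 ± 0.27), Ephrin (1.80 ± 0.08) and NfI (1.45 ± 0.19) rose and the pigmentation-family gene yellow-h fell by 1.17. All 3 arrays lay above the wildtype range (exact two-sided permutation p = 0.0119, as for arms 2R and 3L; limma camera adjusted p = 0.00504, and adjusted p = 0.587 with an estimated correlation; percentile 99.02 of matched lists). Without array A the value was 0.16 (limma adjusted p = 0.0526). Pericentromeric genes were not called (relative mean -0.05, limma adjusted p = 0.386; -0.10 without array A and -0.02 without array C), with 17 up and 72 down (18 and 72 adjusted over the list alone). The longest and shortest groups were not separated by the test (mean difference -0.17, median difference 0.05, adjusted p = 0.328, exact permutation p = 0.0952), and the mean difference ran from -0.28 without array A to -0.09 without array C.

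**Figure D2:**
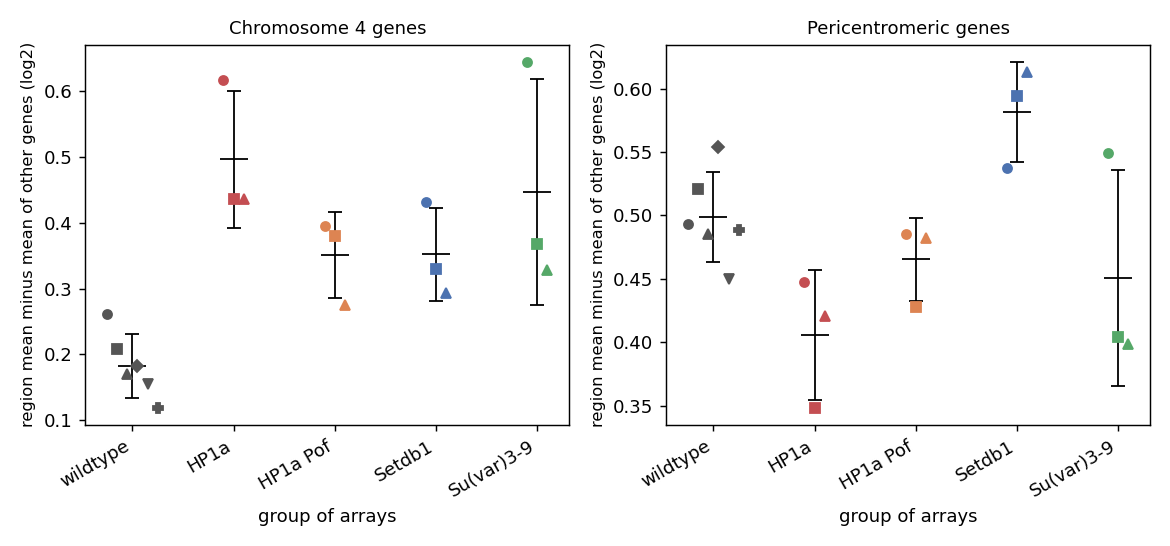
Mean log2 level of chromosome 4 genes (55) and of pericentromeric genes (129) minus that of all other tested genes, on each of 18 arrays (circle, square and triangle are replicates A to C, diamond, inverted triangle and plus are D to F; lines give the group mean and SD). Every mutant array lies above the wildtype arrays for chromosome 4, while for the pericentromeric genes the group means lie between 0.41 and 0.58 and the HP1a mutant arrays lie below the wildtype arrays.

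The arrays labelled HP1a Pof double mutant shared cuticle, digestive, detoxification and neuronal changes with HP1a mutants when set against wildtype. Of 8211 genes 2055 were higher and 2938 lower (limma), 502 and 639 by at least 2-fold. Centring each array on the median of its genes gave 2636 higher and 2566 lower. Arrays did not overlap for 62.6% of genes (2.38% by chance). Cuticle protein genes rose in 54 cases of 85 and fell in 8 (55 and 8 adjusted over the list alone; relative mean 1.53, adjusted p = 1.8e-08, and adjusted p = 0.665 with an estimated correlation), led by Cpr49Ad (4.40 ± 0.16). Digestive enzyme genes fell in 32 cases of 38 and rose in 3 (32 and 3 adjusted over the list alone; relative mean -1.06, adjusted p = 2.78e-07, and adjusted p = 0.665 with an estimated correlation). Detoxification genes fell in 67 cases of 92 and rose in 11 (67 and 11 adjusted over the list alone; relative mean -0.79, adjusted p = 4.88e-07, and adjusted p = 0.665 with an estimated correlation), with Cyp12d1-d at -5.22 ± 0.11, GstE5 at -4.38 ± 0.13 and Cyp9c1 at -3.62 ± 0.08. The 3' 18S control signal was 9.81 ± 0.18 (SD, n = 3) on these arrays. Neuronal genes rose in 14 cases of 24 and fell in 2 (14 and 2 adjusted over the list alone; relative mean 0.62, adjusted p = 0.00079, and adjusted p = 1 with an estimated correlation), with VAChT at 2.36 ± 0.25 and the calcium channel gene cac at 1.32 ± 0.27.

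Smaller shifts in the arrays labelled HP1a Pof double mutant included 25 of 69 mitochondrial ribosomal protein genes up and 3 down (24 and 3 adjusted over the list alone; relative mean 0.18, limma camera adjusted p = 0.00368, and adjusted p = 1 with an estimated correlation). In the oxidative phosphorylation list 30 of 60 genes fell and 0 rose (29 and 0 adjusted over the list alone), among them the succinate dehydrogenase gene SdhD (-0.58 ± 0.06) and ND-20 (-0.60 ± 0.08). Its relative mean was -0.12, with adjusted p = 0.0181, and adjusted p = 1 with an estimated correlation, and centring the arrays ended that call (adjusted p = 0.186). Means of probe sets (-0.05, limma adjusted p = 0.0517) and wildtype arrays A to C alone (-0.09, adjusted p = 0.0666) ended it too. Of 24 DNA replication and cell cycle genes 12 rose and 2 fell (12 and 2 adjusted over the list alone; 0.28, adjusted p = 0.0286, and adjusted p = 1 with an estimated correlation), with CycB3 at 0.87 ± 0.16 and Mcm3 at 0.77 ± 0.11; without array A of that group the list was not called (0.22, adjusted p = 0.0927). A filter at log2 8 (0.31, limma adjusted p = 0.154) and wildtype arrays A to C alone (0.25, adjusted p = 0.0551) also ended that call. Of 14 Hox and Polycomb target genes 9 rose and 0 fell (9 and 0 adjusted over the list alone; 0.46, adjusted p = 0.0135, and adjusted p = 0.665 with an estimated correlation). Of 12 chaperone genes 7 rose and 2 fell (8 and 2 adjusted over the list alone; 0.35, adjusted p = 0.0211, and adjusted p = 0.665 with an estimated correlation).

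On chromosome 4 the arrays labelled HP1a Pof double mutant lay 0.17 above wildtype relative to other genes, which was not called by camera (limma, adjusted p = 0.149) although all 3 arrays lay above the wildtype range (exact two-sided permutation p = 0.0119, as for every other arm). The mean lay at percentile 94.04 of matched lists. Without a filter on low values the shift was 0.18 with limma adjusted p = 0.0486. There were 15 genes up and 13 down (15 and 13 adjusted over the list alone). Rnf11 (3.35 ± 0.27) and toy (1.89 ± 0.22) rose, and CG31999 (-1.65 ± 0.11) and mav (-1.45 ± 0.12), a TGF-beta ligand gene, fell. Pericentromeric genes were not called (-0.03, limma adjusted p = 0.553), with 29 up and 52 down (29 and 53 adjusted over the list alone), among them the chitinase gene Cht10 (-2.32 ± 0.26). The longest genes lay 0.34 above the shortest in log2 change, with 576 long genes up and 320 down and 267 short genes up and 754 down (adjusted p = 6.88e-10, and adjusted p = 0.359 with an estimated correlation; exact two-sided permutation p = 0.0119).

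**Figure D3:**
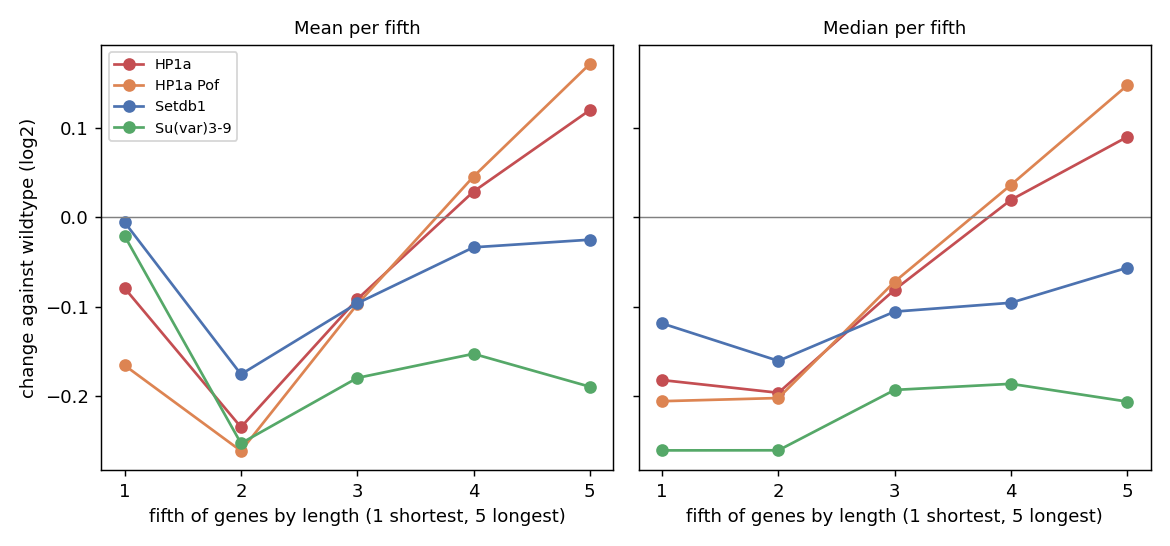
Mean and median log2 change against wildtype of tested genes in 5 equal groups by length, from the shortest to the longest, for the 4 mutant groups. In HP1a mutants and in the arrays labelled HP1a Pof double mutant the longest group has means of 0.12 and 0.17, whereas in Setdb1 and Su(var)3-9 mutants it has means of -0.02 and -0.19.

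The arrays labelled HP1a Pof double mutant were also set against HP1a mutants. Few genes differed: 20 were higher and 40 lower (limma), with 557 at an unadjusted p under 0.05, and arrays did not overlap for 11.1% of genes against 10% by chance. Of the 60 called genes 40 lay on arm 2R, which also carries Pof. The detoxification genes Cyp9c1 (-3.37 ± 0.09), GstE5 (-2.46 ± 0.15) and GstE1 (-2.43 ± 0.11) and Pepck2 (-2.35 ± 0.31), a gluconeogenic gene, were lower, and CG30458 (-4.23 ± 0.44) was lowest. Higher genes included the antimicrobial peptide gene Mtk (1.51 ± 0.33), Cyp6a8 (1.47 ± 0.28, limma adjusted p = 0.0153, and 0.0521 with the replicate letter as a block), Pof itself (1.27 ± 0.21) and LBR (1.23 ± 0.21), which encodes the lamin B receptor. The count rested on single arrays in part: it was 38 without array A and 39 without array B of the double mutant label, 146 with array weights and 23 when only these 6 arrays were fitted.

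Chromosome 4 genes were lower in the arrays labelled HP1a Pof double mutant than in HP1a mutants by 0.15 relative to other genes. mav (-1.24 ± 0.14) and CG31999 (-1.18 ± 0.13) were the 2 called members (0 up and 4 down adjusted over the list alone), and 43 of the 55 genes had a negative change. limma camera gave adjusted p = 2.21e-06, and adjusted p = 0.587 with an estimated correlation. All 3 arrays of the label lay below all 3 HP1a mutant arrays (exact two-sided permutation p = 0.1, the smallest that 10 splits can give). The shift was -0.09 without HP1a mutant array A. Pericentromeric genes had a relative mean of 0.06 with 0 called members (adjusted p = 0.023, and adjusted p = 0.862 with an estimated correlation). That call ended without HP1a mutant array B (0.03, limma adjusted p = 0.481) and without array A or C of the double mutant label (0.05 and 0.05, adjusted p = 0.205 and 0.143). The longest genes lay 0.14 above the shortest (adjusted p = 4.61e-07, and adjusted p = 0.359 with an estimated correlation; exact permutation p = 0.2), and 0.07 above them without HP1a mutant array C.

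Gene lists differed little between these 2 genotypes. Detoxification genes had a relative mean of -0.18, with 2 up and 4 down (4 and 16 adjusted over the list alone; limma camera adjusted p = 8.36e-05, and adjusted p = 0.79 with an estimated correlation). Antimicrobial and humoral immune genes had a relative mean of 0.35, with 1 up, Mtk, and 0 down (3 and 0 adjusted over the list alone; adjusted p = 0.0029, and adjusted p = 0.715 with an estimated correlation, and 0.0523 without HP1a mutant array B at 0.29). Neuronal genes had a relative mean of 0.21 with 0 called members (0 adjusted over the list alone; adjusted p = 0.000425, and adjusted p = 0.989 with an estimated correlation, and 0.052 without HP1a mutant array C at 0.10). Haemocyte genes stood at -0.15 with 0 called members (0 up and 3 down adjusted over the list alone; adjusted p = 0.0155, and adjusted p = 0.715 with an estimated correlation). That call ended without HP1a mutant array C (-0.09, limma adjusted p = 0.207) or array C of the double mutant label (-0.11, adjusted p = 0.0995). The named chromosome 4 list stood at -0.11, with 1 down (2 adjusted over the list alone), and the named pericentromeric list at 0.10 with 0 called members (0 adjusted over the list alone). Their adjusted p was 0.0029 and 0.0247, with adjusted p = 0.989 for both with an estimated correlation. The named chromosome 4 call ended without HP1a mutant array A (-0.03, limma adjusted p = 0.32) or array C of the double mutant label (-0.07, adjusted p = 0.0969), and the pericentromeric one without HP1a mutant array B (0.05, adjusted p = 0.505) or array A of the label (0.06, adjusted p = 0.248). Cuticle genes stood at -0.16 with 1 down, Cpr49Ad (0 up and 1 down adjusted over the list alone; adjusted p = 0.0197, and adjusted p = 0.999 with an estimated correlation). The cuticle sign turned without HP1a mutant array C (0.04, limma adjusted p = 0.983) or array A of the double mutant label (0.06, adjusted p = 0.958), and the call ended without array B of the label (-0.05, adjusted p = 0.215). The cuticle proteins stood at -0.30 without HP1a mutant array A and at -0.50 without array C of the label, and the neuronal genes at 0.35 without HP1a mutant array A.

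**Figure D4:**
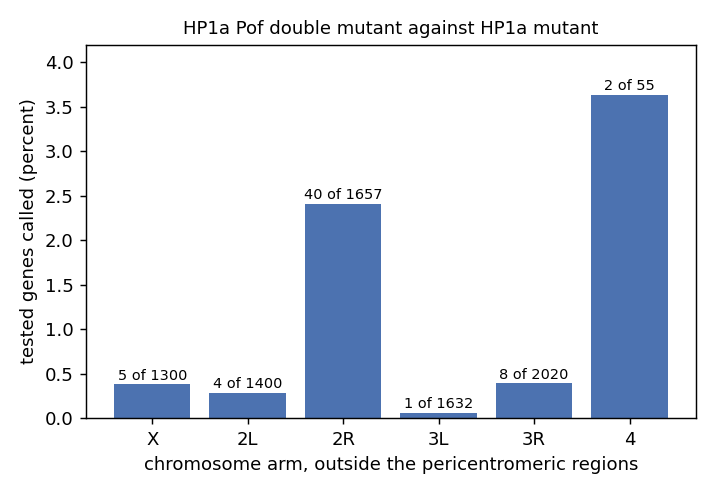
Percent of tested genes called between the arrays labelled HP1a Pof double mutant and HP1a mutants on each chromosome arm outside the pericentromeric regions, with the called and tested numbers above each bar. Arm 2R holds 40 called genes of 1657 (2.41%) and arm 3L holds 1 of 1632.

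Many genes changed against wildtype in more than 1 mutant genotype, and 672 were higher and 1857 lower in all 4 groups, or 1144 and 1266 with each array centred on its median. HP1a and Setdb1 mutants shared 1084 higher and 2233 lower genes, against 333 and 1029 for independent lists, with 59 called in opposite directions. HP1a and Su(var)3-9 mutants shared 912 and 2436 (314 and 1393 for independent lists, 162 opposite), and Setdb1 and Su(var)3-9 mutants 863 and 2438 (231 and 1376, 112 opposite). After centring the pairs shared 1606 and 1730, 1545 and 1714, and 1482 and 1553 (631 and 682, 718 and 739, and 614 and 624 for independent lists), nearly even in direction. These comparisons use the same 6 wildtype arrays. Unchanged groups simulated against those controls shared 0 genes in each direction for each pair, a value that leaves out the effects and tests nothing about sharing. With the wildtype arrays split between the genotypes, the shared counts were 780 and 1709, 703 and 1915, and 640 and 1789, where independent lists of those sizes gave 218 and 728, 207 and 935, and 144 and 870. Both parts are wildtype arrays, which the first principal component set apart from all mutant arrays. The split therefore cannot part effects of the mutations from a difference common to the wildtype arrays. The correlations of log2 changes across genes, which are not independent replicates, were 0.836, 0.778 and 0.768, with 0.329, 0.344 and 0.326 in the simulations. The covariances were 0.44, 0.45 and 0.42, with 0.44, 0.45 and 0.41 for split controls and 0.0092, 0.0096 and 0.0091 in the simulations.

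Direct comparisons asked where the single genotypes differ. The main fit takes the spread of a gene from all groups, including the wildtype arrays, which resembled each other more closely. Counts between mutant groups can therefore be too high. Fits of the compared arrays alone avoid this but have fewer residual degrees of freedom. HP1a and Setdb1 mutants differed in 1517 genes (693 higher and 824 lower in HP1a mutants, limma; 30.9% did not overlap, 10% by chance). Without HP1a mutant array A the count was 951, without Setdb1 mutant array B it was 819, and with these 6 arrays alone it was 336. HP1a and Su(var)3-9 mutants differed in 3292 genes, 2313 higher and 979 lower in HP1a mutants, or 1274 and 1651 with each array centred on its median (39.2% did not overlap, 10% by chance). Without Su(var)3-9 mutant array C the count was 1939, and with the 6 arrays alone 758. Setdb1 and Su(var)3-9 mutants differed in 2255 genes, 1559 higher and 696 lower in Setdb1 mutants, or 861 and 1051 after centring (32.2% did not overlap, 10% by chance), with 1492 left without Su(var)3-9 mutant array C and 546 with the 6 arrays alone. Chromosome 4 genes did not differ by the test in any of these pairs, with relative means of 0.14, 0.05 and -0.09 (limma camera adjusted p = 0.107, 0.932 and 0.107), but single arrays moved these values. All 3 HP1a mutant arrays lay above all 3 Setdb1 mutant arrays (exact permutation p = 0.1, the smallest possible), and the chromosome 4 shift of HP1a against Setdb1 mutants was called without Setdb1 mutant array A (0.18, limma adjusted p = 0.0334) and without a filter (0.14, adjusted p = 0.0408), but not with the replicate letter as a block (0.14, adjusted p = 0.117). It was 0.08 without HP1a mutant array A. The chromosome 4 shift of HP1a against Su(var)3-9 mutants was 0.15 without Su(var)3-9 mutant array A and -0.01 without array C or without HP1a mutant array A. The chromosome 4 shift of Setdb1 against Su(var)3-9 mutants was called without Setdb1 mutant array A (-0.13, limma adjusted p = 0.0334) and without Su(var)3-9 mutant array B or C (-0.13 and -0.15, adjusted p = 0.0498 and 0.0149), and was 0.00 without Su(var)3-9 mutant array A.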

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

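The tests of RNA integrity, of the 18S control probe sets, of the share on chromosome 2 and of the share on arm 2R were chosen after the results they test were seen.

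Mutant groups differed from each other in several gene groups by limma camera at the preset correlation. None of these calls was kept with an estimated correlation (adjusted p = 0.25 or more). That setting kept no list call in any comparison, cuticle proteins against wildtype included, so it does not single out the calls given here. HP1a against Setdb1 mutants differed in pericentromeric genes (-0.18) and in long against short genes (0.22). They also differed in heterochromatin factors (0.18), oxidative phosphorylation (-0.13), DNA replication (0.29), digestive enzymes (-0.37) and neuronal genes (0.46). HP1a against Su(var)3-9 mutants differed in long against short genes (0.37), heterochromatin factors (0.19), mitochondrial ribosomal proteins (0.15), oxidative phosphorylation (-0.18) and DNA replication (0.24). The same pair differed in antimicrobial genes (-0.56), detoxification (-0.43), digestive enzymes (-0.68), cuticle proteins (-0.43), muscle (-0.11) and neuronal genes (0.58). Without Su(var)3-9 mutant array A the muscle call ended (-0.02, limma adjusted p = 0.187), and without Setdb1 mutant array C the length difference between HP1a and Setdb1 mutants was 0.14. Setdb1 against Su(var)3-9 mutants differed in pericentromeric genes (0.13), mitochondrial ribosomal proteins (0.21), antimicrobial genes (-0.30), chaperones (-0.46), detoxification (-0.30), digestive enzymes (-0.32) and cuticle proteins (-0.29). Single arrays ended 4 of these calls. The cuticle call ended without Setdb1 mutant array B (-0.13, limma adjusted p = 0.117) or Su(var)3-9 mutant array C (-0.20, adjusted p = 0.175), while the shift of cuticle proteins was -0.55 without Setdb1 mutant array C. The digestive call ended without Setdb1 mutant array C (-0.20, adjusted p = 0.147) or Su(var)3-9 mutant array B or C (-0.24 and -0.27, adjusted p = 0.0806 and 0.0999). The antimicrobial call ended without Setdb1 mutant array B or C (-0.33 and -0.25, limma adjusted p = 0.07 and 0.147) or Su(var)3-9 mutant array B or C (-0.23 and -0.26, adjusted p = 0.0806 and 0.175). The chaperone call ended without array A or B of Setdb1 mutants (-0.43 and -0.44, limma adjusted p = 0.0624 and 0.136) or of Su(var)3-9 mutants (-0.49 and -0.44, adjusted p = 0.114 and 0.0729).

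Processing choices ended several of the same calls. With boundaries moved by 1 Mb the pericentromeric shift was -0.04 for HP1a against Setdb1 mutants and 0.08 for Setdb1 against Su(var)3-9 mutants (limma adjusted p = 0.387 and 0.166), and a filter at log2 8 ended the latter too (0.10, adjusted p = 0.0612). That filter also ended the heterochromatin call of HP1a against Setdb1 mutants (0.17, limma adjusted p = 0.0804). For HP1a against Su(var)3-9 mutants centring and array weights ended the cuticle call (-0.43 and -0.26, limma adjusted p = 0.0545 and 0.0923). No filter, cyclic loess and array weights ended the muscle call there (-0.04, -0.04 and -0.05, limma adjusted p = 0.109, 0.168 and 0.124). For Setdb1 against Su(var)3-9 mutants the cuticle call ended without a filter, with loess, with centring and with these 2 groups alone (limma adjusted p = 0.0959, 0.229, 0.24 and 0.118), and the digestive call with loess and centring (adjusted p = 0.1 and 0.144). The antimicrobial and chaperone calls of that pair ended with a filter at log2 8 (both limma adjusted p = 0.121), means of probe sets (0.0501 and 0.0667), loess (0.209 and 0.1), centring (0.228 and 0.0895) and a robust trend (both 0.0519), and the antimicrobial call also without a filter (0.0959).

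Probe sets without a named gene also changed. Of 4720 such probe sets 991 were bright enough to be tested. Those higher than wildtype by at least 4-fold numbered 23 in HP1a mutants, 14 in Setdb1 mutants, 27 in Su(var)3-9 mutants and 23 in the arrays labelled HP1a Pof double mutant, and those lower by as much 5, 5, 5 and 7. All called by limma were 241 higher and 230 lower, 165 and 245, 229 and 374, and 249 and 223.

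Cuticle protein genes were called higher in every mutant group and digestive and detoxification genes lower in all but Su(var)3-9 mutants (adjusted p = 0.228 or more with an estimated correlation), and RNA integrity, larval timing or a batch of control arrays could each produce such a pattern. The 3'-minus-5' difference was 0.24 lower in mutant than in wildtype arrays (-0.24, exact two-sided permutation p = 0.0225), which is the direction of better preserved mutant RNA. That test pooled all mutant genotypes, and HP1a mutants lay near wildtype (1.64 and 1.67). The GAPDH control went the other way in HP1a mutants (1.39) and in the arrays labelled HP1a Pof double mutant (1.27), against 1.12 in wildtype. It was 1.10 in Setdb1 and 1.14 in Su(var)3-9 mutants. Over the 6 wildtype arrays the cuticle and digestive means had a Pearson r of 0.179 (exact permutation p = 0.818) and a Spearman rho of -0.2 (exact permutation p = 0.714), and r was 0.601 without the 2 farthest arrays (n = 4). Wildtype and mutant arrays did not overlap in 2 of 3 probe sets for 18S ribosomal RNA, with gaps of 1.07 and 0.41, and overlapped by 1.40 in the other (-1.40). Larval timing and an array batch both remain open. RNA integrity is not settled either. In HP1a mutants and the arrays labelled HP1a Pof double mutant the control transcripts disagreed. In Setdb1 (1.25 ± 0.09) and Su(var)3-9 mutants (1.32 ± 0.13) the mean lay furthest from wildtype (1.67 ± 0.15). The test asked only whether mutant RNA was less well preserved, so it cannot exclude effects of less well preserved wildtype RNA.

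Genes with large falls often lay on chromosome 2, which carries the mutated genes of the HP1a and Setdb1 strains, and linked strain background may contribute. Of 121 genes lower by at least 4-fold in HP1a or Setdb1 mutants 50.4% lay on chromosome 2, against 33.3% of 72 in Su(var)3-9 mutants (Fisher exact p = 0.0247, odds ratio 2.03). Genes lower in both, such as Cyp6w1, were counted on each side, and both lists use the same wildtype arrays. Fisher's test takes the lists as separate, so that p does not hold as stated. Large rises from wildtype showed no such excess: 25.5% in HP1a and 23.6% in Setdb1 mutants lay on chromosome 2, against 37.8% of tested genes. They lay often on chromosome 3, which holds 45.3% of tested genes. The shares there were 60.1% in HP1a, 60.8% in Setdb1 and 59.6% in Su(var)3-9 mutants, and 54.7% in the arrays labelled HP1a Pof double mutant. An excess on a chromosome thus also arose away from the mutated gene. Of the large falls in Su(var)3-9 mutants 54.2% lay on chromosome 3. Between the arrays labelled HP1a Pof double mutant and HP1a mutants 66.7% of 60 called genes lay on arm 2R, against 20.2% of the other genes (Fisher exact p = 1.12e-14, odds ratio 7.91), 13 of them higher and 27 lower. Strain variants under the probes could be examined in 1 gene only, CG10205, where the other probe set fell too (-2.01 and -1.74, 100% of 1 gene).

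Chromosome 4 genes were lower in the arrays labelled HP1a Pof double mutant than in HP1a mutants, which could rest on a few genes, on expression level or on 1 array. Without the 5 largest changes the mean of the other 50 genes was -0.08, at percentile 1.93 of 10000 random lists matched on level. All 55 genes lay at percentile 0.03. Random lists do not carry the correlation among chromosome 4 genes, estimated at 0.285, so these percentiles treat the genes as independent. With that correlation limma camera gave adjusted p = 0.587. Leaving out single arrays left the shift at -0.0854 or lower.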

How the results depend on the processing

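The alternative with Su(var)3-9 mutant array A alone was chosen after arrays B and C were seen to stand apart. Of the alternatives, 198 of 223 for counts, 442 of 485 for position and length, 3504 of 3719 for lists and 9681 of 9986 for named genes left a count within 1.5-fold or a call as it was. Values without a call could still turn in sign. Where a value moved, the cause was not tested.

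An added minimum change of 0.58 left 2341, 1800, 2512 and 2515 genes for HP1a, Setdb1 and Su(var)3-9 mutants and the arrays labelled HP1a Pof double mutant against wildtype. It left 611, 1385 and 912 between the single genotypes (HP1a and Setdb1, HP1a and Su(var)3-9, Setdb1 and Su(var)3-9) and shared sets of 1380, 1460 and 1316. With only the 2 groups fitted, the arrays labelled HP1a Pof double mutant differed from HP1a mutants in 23 genes, and the single genotypes in 336, 758 and 546. Array weights gave 146 for the first of these.

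With an estimated correlation 0 gene lists were called, against 32 in the comparisons with wildtype and of the arrays labelled HP1a Pof double mutant with HP1a mutants, and over all 8 comparisons 53 of 200 results lost their call. The shifts stayed as they were but lost their calls: chromosome 4 at 0.31, 0.17, 0.26 and -0.15 (limma adjusted p = 0.587), length at 0.20, 0.34 and 0.14 (limma adjusted p = 0.359) and the pericentromeric shift at 0.0596 (limma adjusted p = 0.862). That pericentromeric shift was 0.0346 without a filter, 0.0487 with array weights and 0.0387 with boundaries moved by 1 Mb. Without a filter the chromosome 4 shift in the arrays labelled HP1a Pof double mutant against wildtype was called (0.18). A filter at log2 8 ended the call in Setdb1 mutants (0.0877).

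With the replicate letter as a block the chromosome 4 shift in Setdb1 mutants was 0.14 (limma adjusted p = 0.0607). Against wildtype the block also took wildtype arrays D to F out of the comparison. Calls that ended there may therefore reflect fewer controls and not pairing. In comparisons with same-letter correlations above 0.1 the block also ended the chaperone call in HP1a mutants and the muscle call in Su(var)3-9 mutants. The block ended as well the calls of Pof in Setdb1 mutants and of Cyp6a8 in the arrays labelled HP1a Pof double mutant against HP1a mutants. It changed no other call printed for these comparisons.

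The length difference in Setdb1 mutants turned positive with the longest and shortest of 3 groups (0.0519) and with means of probe sets (0.000282). Means of probe sets turned mod(mdg4) (0.0382), Ald1 (-0.0409) and egr (0.0409) in HP1a mutants, sls (0.0254) in Su(var)3-9 mutants, and Ald1 (-0.0172) and egr (0.0520) in the arrays labelled HP1a Pof double mutant. The muscle list in Su(var)3-9 mutants turned without a filter (-0.0403) and with cyclic loess (-0.00461).

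With Su(var)3-9 mutant array A alone the spread came only from the other groups, so these counts do not test that genotype. There 3459 genes differed from wildtype, 573 from HP1a mutants and 990 from Setdb1 mutants, and the length difference was 0.0630. Pof (-0.42), ovo (0.0323), the chromosome 4 shift of HP1a against Su(var)3-9 mutants (-0.15) and the length difference of Setdb1 against Su(var)3-9 mutants (-0.0824) turned.

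Leaving out 1 array at a time moved the chromosome 4 shift between 0.13 (without Setdb1 mutant array A) and 0.20 in Setdb1 mutants, and between 0.16 (without Su(var)3-9 mutant array A) and 0.32 in Su(var)3-9 mutants. The length difference in Setdb1 mutants ran from -0.10 (without Setdb1 mutant array A) to 0.0630 (without Setdb1 mutant array C). The arrays labelled HP1a Pof double mutant differed from HP1a mutants in 38 genes (without array A of that label) to 67 (without HP1a mutant array A). Their pericentromeric shift ran from 0.0311 (without HP1a mutant array B) to 0.0806 (without HP1a mutant array A), the proteasome list from -0.0594 (without HP1a mutant array A) to 0.15 (without HP1a mutant array B), and the cuticle list from -0.50 (without array C of the label) to 0.0601 (without array A of the label). HP1a and Setdb1 mutants differed in 819 (without Setdb1 mutant array B) to 1505 genes (without Setdb1 mutant array C). Against Su(var)3-9 mutants the counts ran from 1939 to 3885 for HP1a mutants and from 1492 to 2657 for Setdb1 mutants, lowest without Su(var)3-9 mutant array C and highest without array A.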

Other observations

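No test in this part was chosen after its result was seen.

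Hormone response genes split in all mutant groups without the list being called. Of 23 ecdysone genes, 3 rose and 7 fell in HP1a mutants (3 and 6 adjusted over the list alone), 3 and 7 in Setdb1 mutants, 4 and 13 in Su(var)3-9 mutants, and 6 and 7 in the arrays labelled HP1a Pof double mutant (limma camera adjusted p = 0.97, 0.89, 0.891 and 0.839). The receptor gene EcR rose by 1.21 and br by 0.85 in HP1a mutants, while Hr3 fell by 1.27 and E23 by 1.46 in Su(var)3-9 mutants.

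Blood cell and immune genes moved in both directions. Of 11 haemocyte genes 4 rose and 6 fell in HP1a mutants (4 and 6 adjusted over the list alone), with the collagen genes Col4a1 (1.09 ± 0.06) and vkg (0.93 ± 0.06) higher and the prophenoloxidase genes PPO1 (-1.08 ± 0.13) and PPO2 (-0.90 ± 0.10) lower. The haemocyte list was not called against wildtype in any group (limma camera adjusted p = 0.97, 0.89, 0.61 and 0.668). Of 15 antimicrobial genes 3 rose and 6 fell in HP1a mutants (3 and 6 adjusted over the list alone; not called, limma adjusted p = 0.56), with Drs at 1.75 ± 0.36 and pirk, a brake on the Imd pathway, at -1.37 ± 0.17.

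In HP1a mutants the other lists were not called against wildtype. The numbers higher and lower were 3 and 3 of 12 fat body genes, 3 and 2 of 6 germline genes, 2 and 1 of 5 spermatogenesis genes, 0 and 1 of 6 yolk and chorion genes, 3 and 3 of 10 dosage compensation genes, and 2 and 5 of 12 apoptosis and DNA damage genes (the same numbers adjusted over the list alone, save 4 lower dosage compensation genes). The limma camera adjusted p was 0.542 for germline genes and 0.97 for the others. Without a filter the germline list was called in HP1a mutants (0.20, limma adjusted p = 0.0463) and the spermatogenesis list in Su(var)3-9 mutants (0.85, adjusted p = 2.64e-11, against 0.37 and 0.242 with it). Ribosomal protein genes (3 and 2 of 37, 0 and 1 adjusted over the list alone) and proteasome genes (1 and 9 of 26, 1 and 8 adjusted over the list alone) were not called either (limma camera adjusted p = 0.553 and 0.6). UGP rose by 1.08, spn-E by 0.63 and bol by 0.59, while Gadd45 fell by 1.00, ix by 0.86 and Yp3 by 0.58. No Y-linked gene was tested (7 on the array). Genes on the X chromosome were not called in any group (relative means 0.03, -0.01, -0.03 and 0.04, limma camera adjusted p = 0.935). The exact two-sided permutation p over arrays was 0.0238, 0.488, 0.107 and 0.0119.

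Counts of called genes were set against other splits of the same arrays, each fitted with its 2 groups only. For the HP1a comparison with wildtype the real split gave 5261 genes and was the 1 of 84 splits with so many, and the highest other gave 1. For Setdb1, Su(var)3-9 and the arrays labelled HP1a Pof double mutant the real counts were 4744, 5400 and 5738, each the 1 of 84 splits with so many, and the highest others gave 0. Comparisons between mutants allow 10 splits only, which are too few. There the real counts were 23, 336, 758 and 546 and the highest others 81, 42, 0 and 0. For the arrays labelled HP1a Pof double mutant against HP1a mutants 2 of 10 splits had as many genes as the real one, and the highest parted 1 pair of replicate letters, while the 3 other splits that part all 3 pairs gave at most 0.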
